A study of Oryza sativa with 8 samples.

How the data were processed

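RNA-seq was used to measure gene expression in rice (Oryza sativa) seedlings of the MH63 variety. Per the labels' protocols, seedlings were grown for 14 days with ample water, and drought was then imposed by withholding water for 15 days, with the relative soil water content kept near 5% at the end. Recovery samples were taken after 4 further days of watering. RNA was isolated with a Qiagen plant column kit, and libraries were prepared with an Illumina TruSeq RNA kit, per the labels' protocols. The 8 samples formed 4 groups of 2, namely normally watered wild type, drought-treated wild type, rewatered wild type and drought-treated osbzip23 plants. The labels state that the treatment was carried out on separate batches of seedlings, but do not say that a replicate number marks a batch. The p-values therefore measure the spread between these samples only.

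The deposited table held whole-number counts per gene, 1 column per sample, per the file headers, with no normalization by the authors. The submitters' processing notes name fastp 0.23.0, STAR 2.7.10a and StringTie 2.1.7, without a role or an order for each. The genome build, the annotation, the strand setting and the treatment of reads shared between gene copies were not given in the sources used here. Counts of paralogous or overlapping genes are therefore uncertain. The table had 59903 rows, each named by a gene ID, of which 19292 held no count in any library. None of these IDs matched a reference table of 39387 rice genes from another assembly (0 matches), and the counts table pairs no ID with a name. For that reason 18 gene lists with 174 symbols and 21 families of gene descriptions, fixed before the data were examined, were not tested, and the level of bZIP23, the gene disrupted in the osbzip23 plants, is not reported here. The mutant labels were thus not checked against the targeted gene.

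Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter by group and the two-sided quasi-likelihood F-test. All 8 samples entered a single fit with 4 residual degrees of freedom, and 4 contrasts were taken from it. The p-values were adjusted by the Benjamini-Hochberg method within each contrast over 33074 tested genes, and a gene was called at an adjusted p under 0.05. Fold changes are log2 values with standard errors from the fit. CPM values are the deposited counts scaled to a library total of 1000000, without TMM, and are given as mean ± SD. A fold set against 1 to 3 counts is given with its 95% counting interval, and a fold set against 0 counts with a floor of 3 counts over the group. Intervals and floors cover counting error only. Named rows were chosen by a rule fixed before the data were examined, which allowed, for IDs without names, up to 2 that rose and 2 that fell per comparison, those with the largest fold among called rows with a mean log2 CPM of at least 3 and groups that did not overlap.

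The correspondence of rows between libraries was checked with Pearson correlations of log2(CPM + 1) across rows, with 1000 shuffles of the osbzip23 rows, and with blocks of 200 rows shifted by up to 300 rows and, added after seeing the data, by up to 6000 rows (Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3). Because these checks set the osbzip23 libraries apart, a fit of the 6 wild type libraries alone, over 22898 genes, and 10 fits with shuffled osbzip23 rows were added after seeing the data. The shuffling in these fits covered the first 40897 rows, up to the last count of wild type drought replicate 1. The drought-risen and drought-fallen sets were tested in the genotype contrast with camera (limma 3.58.1), with a preset inter-gene correlation of 0.01 and with an estimated one. Comparisons that share libraries were set beside 20 simulations of unchanged groups. The pair of libraries in each group is too small to be divided, so part of any excess over the simulations or over independent lists may come from the shared libraries.

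Other settings, fixed before the data were examined, were median-of-ratios size factors, library size scaling without TMM, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 50 counts in at least 2 samples, a minimum absolute log2 fold change of 1, fits of the 4 samples compared, the replicate number as a block, and each library left out in turn. The procedure was tested on simulated counts in which each gene had the same spread in every library. Among rows with an expected wild type count of at least 50 in a library of average size, 100 genes were changed by 2-fold and 100 by 4-fold. In the 8-library fit of simulated drought against normal, 69% and 95% of these were recovered, with 9 false calls among 32496 genes. For recovery against drought, 57% and 96% were recovered, with 7 false calls. For recovery against normal, the values were 62% and 93%, with 13 false calls. For the genotype contrast, the values were 64% and 98%, with 12 false calls among 22602 genes. In that simulation osbzip23 had the wild type mean on every unchanged row. The deposited columns differ from this, so these rates do not carry over to the genotype comparison below. For the wild type comparisons, the recovery rates do not cover rows with fewer counts. False calls weigh more against the genes recovered than against all genes fitted.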

Results

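Gene expression was measured in whole seedlings of MH63 rice under normal watering, after drought and after rewatering, and in osbzip23 seedlings after drought. OsbZIP23 is a bZIP transcription factor of the abscisic acid response. The wild type libraries held 41401806 and 37400784 counts under normal watering, 41691660 and 42894245 in drought, and 38072531 and 39128352 in recovery. The osbzip23 libraries were shallower, with 14653876 and 17009931 counts. Replicates of a wild type group correlated at r = 0.998 across genes, and the osbzip23 pair at 0.989. The coefficient of variation between replicates beyond counting noise was 6.6% in normal, 7.9% in drought and 6.1% in recovery wild type, against 23.8% in osbzip23. Replicates of each group differed by more than counting noise, with a chi-square per degree of freedom from 4.42 to 24.63, so no pair was treated as a library deposited more than once, which does not show that the libraries came from separate plants.

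Wild type and osbzip23 counts were spread over the gene IDs in different ways. IDs of chromosome 12, 3789 in number, held 4.0% ± 0.0049 of the counts in osbzip23 (SD, n = 2). In wild type they held 0.000411% ± 0.00058 in drought, 0.0168% ± 0.000057 under normal watering and 0.0278% ± 0.000039 in recovery (SD, n = 2 each). IDs of chromosome 11 held 5.7% ± 0.50 in osbzip23 and 1.6% ± 0.0067 in wild type drought. In windows of 200 neighbouring chromosome 12 IDs, 10% to 50.2% of IDs reached 10 counts in osbzip23, against 0.0% to 0.2% in wild type drought. Over the first 40897 rows of the table, the last of which is the final row with a count in wild type drought replicate 1, osbzip23 and wild type drought correlated at r = -0.011 across rows. After shuffling the osbzip23 rows 1000 times, r ran from -0.018 to 0.015, and 984 of the shuffles gave a value at least as high as the observed one. In the same rows the pairs of wild type libraries correlated at 0.906 to 0.998 and the osbzip23 pair at 0.988. The last count of osbzip23 replicate 1 stood on row 45973, and on row 45974 the IDs went from chromosome 12 back to chromosome 1. In what follows, the rows correspond among the 6 wild type libraries, while an ID printed for a wild type value names a row of the table and is not evidence of which gene was measured.

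**Figure D1:**
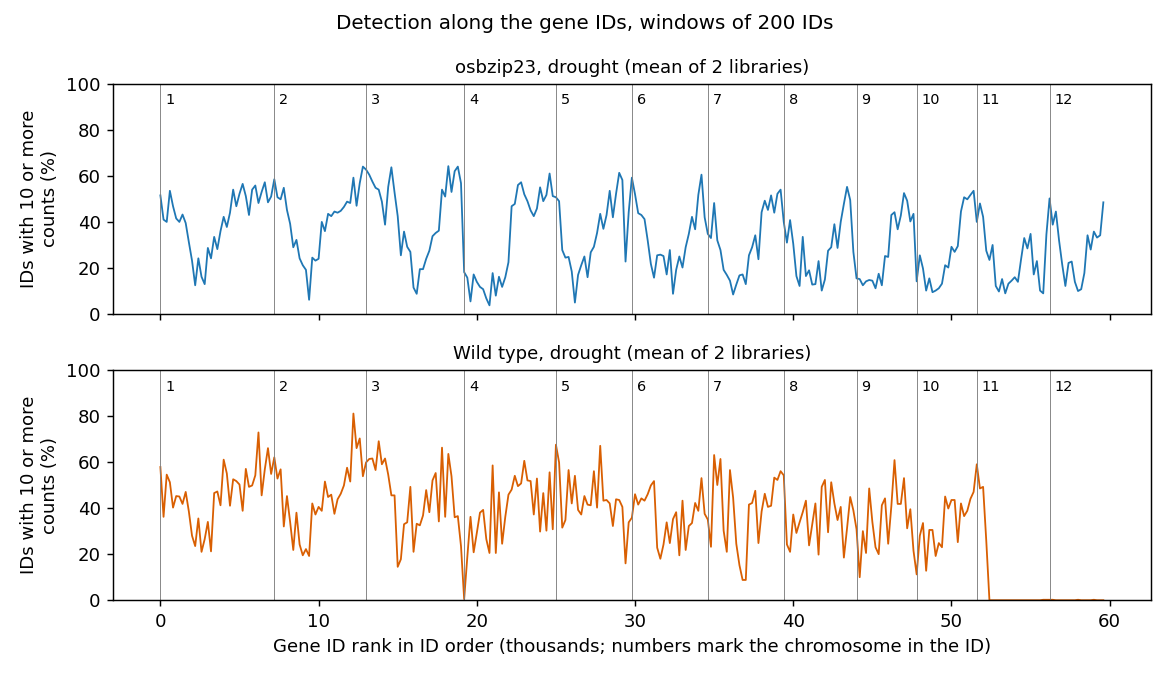
Percent of gene IDs with 10 or more counts (vertical axis) in windows of 200 IDs along the ID order (horizontal axis, rank of the ID in units of 1000 IDs, with the chromosome number in the ID marked), as the mean of 2 libraries for osbzip23 (top) and wild type (bottom) in drought. On chromosome 12 the osbzip23 windows lie between 10% and 50.2%, and the wild type windows between 0.0% and 0.2%.

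Drought against normal watering in wild type asked how the seedling transcriptome responded to water loss. Drought moved a large part of it. Genes that rose in drought made up 21.5% ± 0.030 of all counts in normal plants and 56.9% ± 0.38 in drought (SD, n = 2 each). Genes that fell went from 56.8% ± 0.13 to 21.9% ± 0.069. These sets were chosen on the same libraries, so the shares describe the size of the change and are not a separate test of it. The rise was steepest in 985 genes that rose 8-fold or more, from 0.50% ± 0.0056 to 16.85% ± 0.47 of the counts. The 1925 genes that fell 8-fold or more went from 7.83% ± 0.082 to 0.48% ± 0.0058. The 10 most abundant rows in drought, each called higher, took 8.61% ± 0.19 of the drought counts and 0.897% ± 0.012 of the normal counts.

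The row with ID OsMH_10G0003000 showed the largest rise by the naming rule, at 20550 ± 1050 CPM in drought against 1.13 ± 0.278 CPM under normal watering (SD, n = 2 each). Its log2 fold change was 14.18 ± 0.27 (SE, edgeR quasi-likelihood test, adjusted p = 1.42e-07). The row OsMH_03G0013700 rose from 0.776 ± 0.303 to 1846 ± 107 CPM, with a log2 fold change of 11.24 ± 0.35 (edgeR adjusted p = 2.65e-07). Among the falls, OsMH_07G0101700 went from 1160 ± 37.9 to 0.614 ± 0.121 CPM, a log2 fold change of -10.83 ± 0.12 (edgeR adjusted p = 5.38e-08). The row OsMH_01G0550400 went from 135.8 ± 2.33 CPM to 0 and 3 counts in the drought libraries, a ratio of 3880 with a 95% counting interval of 1310 to 18600 (edgeR adjusted p = 6.07e-08). Its fitted log2 fold change of -11.71 became -10.79 without wild type drought replicate 1 and -15.09 without replicate 2.

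In all, 13955 of 33074 tested genes (42.2%) were called between drought and normal watering, 6441 higher and 7514 lower in drought. The 33074 genes include rows with counts in osbzip23 and none in wild type, which cannot be called in a wild type comparison. Such rows lower the percentages of 33074 in each wild type comparison, and the spread in that fit drew on the osbzip23 libraries too. Where osbzip23 rows do not correspond to wild type rows, part of that spread came from counts of other genes. The common dispersion was 0.0214 in that fit and 0.0056 in the 6 wild type libraries alone. The adjusted p of named wild type rows come from the fit with the osbzip23 libraries and carry the same limit. The median log2 fold change was 1.14 among the risen and -1.67 among the fallen genes. With a minimum absolute log2 fold change of 1 the count was 9042, of which 3693 were higher and 5349 lower. In the 6 wild type libraries alone, 16641 of 22898 genes (72.7%) were called, 8090 higher and 8551 lower, and 13636 of the 13955 genes were called again. Which direction was larger depended on the fit. Median-of-ratios scaling gave 7175 higher and 7119 lower and DESeq2 gave 7983 and 7705, while under every other setting more genes were lower.

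**Figure D2:**
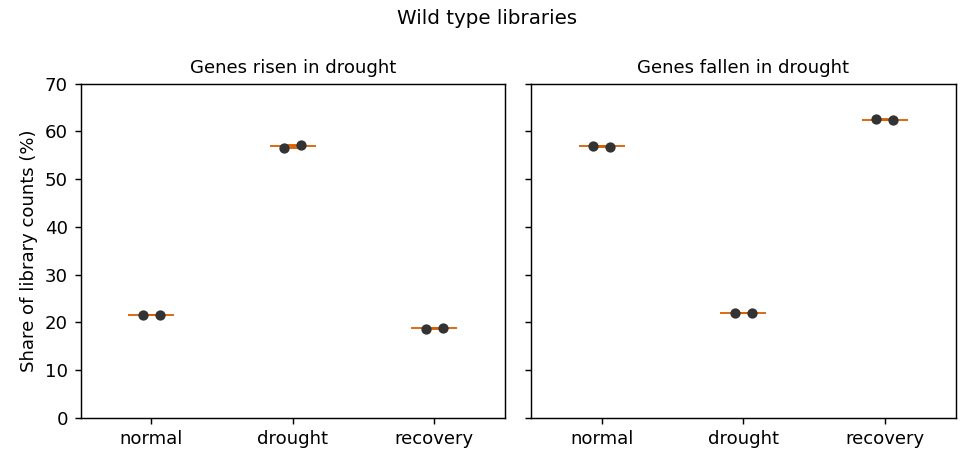
Share of library counts (vertical axis, percent) taken by the genes that rose in drought (left) and those that fell (right) in each wild type library under normal watering, drought and recovery. Dots are libraries, and orange bars are the mean and SD of 2 libraries. The share of risen genes goes from 21.5% to 56.9% and to 18.7%, and that of fallen genes from 56.8% to 21.9% and to 62.5%.

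Recovery against drought asked what 4 days of rewatering undid. The drought-risen genes returned to 18.7% ± 0.059 of the counts, and the drought-fallen genes to 62.5% ± 0.16 (SD, n = 2 each). Genes that had risen 8-fold or more went back to 0.60% ± 0.0023 of the counts. Those that had fallen 8-fold or more reached 11.69% ± 0.072, above their 7.83% ± 0.082 under normal watering. The row OsMH_10G0003000 dropped to 5.73 ± 1.74 CPM, a log2 fold change of -11.67 ± 0.24 against drought (edgeR adjusted p = 1.41e-07). The row OsMH_03G0013700 dropped to 1.26 ± 0.482 CPM (log2 fold change -10.38 ± 0.34, edgeR adjusted p = 2.55e-07). In recovery OsMH_07G0101700 reached 264.1 ± 5.35 CPM, still below its 1160 ± 37.9 CPM under normal watering. The row OsMH_01G0550400 rose to 196.8 ± 2.44 CPM (edgeR adjusted p = 4.98e-08), from the same 3 drought counts, a ratio of 5630 with a 95% counting interval of 1900 to 26900. Its fitted log2 fold change of 12.43 became 11.51 or 15.81 without wild type drought replicate 1 or 2. The row OsMH_02G0137000 rose from 7 and 0 counts in the drought libraries to 158.4 ± 9.33 CPM, a ratio of 1890 with a 95% counting interval of 929 to 4760 (edgeR adjusted p = 5.24e-07). Its fitted log2 fold change of 10.98 ± 0.42 became 15.5 or 10 without wild type drought replicate 1 or 2. Of 33074 genes, 14901 (45.1%) were called, 7824 higher and 7077 lower in recovery. In the 6 wild type libraries alone, 17277 of 22898 genes (75.5%) were called, 8736 higher and 8541 lower. Here too the larger direction depended on the fit. More genes were lower with median-of-ratios scaling (7456 higher, 7799 lower), library size scaling (7198, 8111), DESeq2 (7938, 8448) and the stricter count filter (6896, 7573). Under every other setting more were higher.

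Of the 13955 genes called in drought, 12373 (88.7%) were called in the opposite direction on rewatering. This held for 5687 of 6441 risen genes (88.3%) and 6686 of 7514 fallen genes (89.0%), while 54 genes were called further in the drought direction. Over all tested genes of this fit, independent lists would share 1378 and 1778 genes. Rows that cannot be called in wild type make these expected numbers too small. In the 6 wild type libraries alone, 14953 of 16641 genes were called back. These were 7270 risen and 7683 fallen genes, where independent lists would share 3018 and 3262. Unchanged groups simulated for that fit, which share the drought libraries in the same way, had at most 4 genes called in both with opposite signs. These simulations called at most 13 genes between drought and normal, so their overlap was small by design and is no measure for the observed one. Across 22898 genes of the wild type fit, the fold changes of the 2 comparisons correlated at r = -0.94, against -0.49 in the simulations, with a covariance of -5.09 against -0.046. The simulations share the drought libraries too, so the spread between replicates of these libraries accounts for little of that covariance. A deviation common to both drought libraries was not simulated and may be part of the excess. Genes are not independent replicates.

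Recovery against normal watering asked what remained different after rewatering. Per the labels' protocols, normal plants were harvested together with the drought plants, recovery plants were harvested 4 days later, and no normally watered sample of that later day was analysed here. The row OsMH_01G0046300 stayed above normal, at 64.1 ± 3.27 against 1.03 ± 0.213 CPM, below its 1669 ± 24.1 CPM in drought (SD, n = 2 each). Its log2 fold change over normal was 6.13 ± 0.15 (edgeR adjusted p = 2.46e-06). The row OsMH_01G0639100 stood at 343.7 ± 4.30 CPM in recovery, 13.7 ± 0.862 CPM in normal and 6.68 ± 0.0507 CPM in drought plants, with a log2 fold change over normal of 4.83 ± 0.09 (edgeR adjusted p = 8.93e-07). The row OsMH_10G0105100 remained low, at 33.1 ± 0.365 against 245 ± 5.57 CPM (log2 fold change -2.70 ± 0.08, edgeR adjusted p = 1.65e-05), above its 12.1 ± 0.260 CPM in drought. The row OsMH_01G0115100 was at 2.28 ± 0.301 CPM in recovery against 13.4 ± 0.581 CPM in normal plants (log2 fold change -2.37 ± 0.19, edgeR adjusted p = 0.000485). Its mean in drought was 23.3 ± 1.29 CPM, above normal, so its low recovery value does not carry on a fall seen in drought.

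In this comparison 3231 of 33074 genes (9.8%) were called, 1868 higher and 1363 lower in recovery, and with a minimum absolute log2 fold change of 1 there were 1105, 761 higher and 344 lower. Both the number and the split depended on the fit. In the 6 wild type libraries alone 7968 of 22898 genes (34.8%) were called, 4155 higher and 3813 lower. TMM raised recovery over normal values by 0.18 on the log2 scale relative to library size alone. The calls were 57.8% higher with TMM, 29.2% with library size scaling and 44.0% with the stricter count filter. DESeq2 called 6954 genes, and the fit of the 4 samples compared called 8910. Leaving out a single library gave 628 or 619 genes without normal replicate 1 or 2, 604 or 679 without recovery replicate 1 or 2, 2066 or 2056 without wild type drought replicate 1 or 2, and 6368 or 6517 without osbzip23 replicate 1 or 2.

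Among the 13955 drought-changed genes, 11275 (80.8%) were not called between recovery and normal watering, which does not show that they were equal. In the 6 wild type libraries alone this was 9829 of 16641 genes (59.1%). A further 909 genes were called on the drought side of normal and 1771 beyond it, on the opposite side, and both counts moved strongly with the fit, to 2455 and 4357 in the 6 wild type libraries alone. On the drought side there were 196 or 197 genes without normal replicate 1 or 2, 193 or 214 without recovery replicate 1 or 2, 514 or 497 without wild type drought replicate 1 or 2, and 1874 or 1940 without osbzip23 replicate 1 or 2. Beyond normal, the same omissions gave 327 or 314, 332 or 381, 1105 or 1120, and 3529 or 3585 genes. Over all tested genes of the 8-library fit, independent lists would give 364 and 310 genes on the drought side for the risen and fallen sets. Beyond normal they would give 265 and 424. The observed counts were 481 and 428, and 657 and 1114. Rows that cannot be called in wild type make these expected numbers too small as well. No excess on the drought side is therefore read from this fit. In the 6 wild type libraries alone the observed counts on the drought side were below those of independent lists, 1220 against 1468 for the risen and 1235 against 1424 for the fallen set, while those beyond normal were above, 1933 against 1347 and 2424 against 1552. Fold changes of drought and of recovery, both over normal, correlated at r = 0.07 across 22898 genes, against 0.50 in simulated unchanged groups that share the normal libraries, with a covariance of 0.14 against 0.047. In those simulations, made for the fit of the 6 wild type libraries, no more than 5 genes were called on the same side and 0 on opposite sides. They called at most 12 genes between recovery and normal, so these overlaps were small by design. Part of any excess may come from the shared normal libraries.

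The genotype comparison, osbzip23 against wild type in drought, was meant to show which genes depend on OsbZIP23 under water loss. The number of calls lay inside the range that shuffled rows gave. In the fit, 30691 of 33074 genes (92.8%) were called, 14855 higher and 15836 lower in osbzip23. With the first 40897 osbzip23 rows shuffled, 10 fits called from 30522 to 30766 genes. The other 19006 rows stayed as deposited, so part of this agreement in the number of calls was fixed in advance. The fold changes had medians of 8.94 among the higher and -8.51 among the lower genes on the log2 scale. Named by the fixed rule, the row OsMH_07G0100100 held 12190 ± 3280 CPM in osbzip23 and 1.48 ± 0.113 CPM in wild type drought, and OsMH_06G0417600 held 84.3 ± 3.32 CPM against 2 counts over both wild type libraries, a ratio of 3510 with a 95% counting interval of 987 to 29400 (SD, n = 2 each). The fitted log2 fold change of OsMH_06G0417600, 11.30, became 14.16 or 10.38 without wild type drought replicate 1 or 2. The rows OsMH_10G0003000 and OsMH_07G0098100 had 0 counts in osbzip23 and 20550 ± 1050 and 3069 ± 102 CPM in wild type, at least 217000-fold and 32400-fold lower against a floor of 3 counts over the group. These 4 values are values of rows and are not read as effects of the genotype.

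Drought-changed genes were compared with the genotype calls in the same way. Of 6441 drought-risen genes, 5058 were called lower and 1066 higher in osbzip23, where independent lists would share 3084 and 2893. Of 7514 drought-fallen genes, 2004 were called higher and 4618 lower, against 3375 and 3598. Over both sets 7062 genes were called opposite to drought, and 7035 to 7234 when rows were shuffled. Those called with drought numbered 5684, and 5580 to 5754 when shuffled. The fold changes of both comparisons correlated at r = -0.101 across genes, with -0.110 to -0.100 in the shuffled fits and -0.43 in simulated unchanged groups that share the wild type drought libraries. Their covariance was -1.923, with -2.076 to -1.878 in the shuffled fits and -0.048 in the simulations. By camera, the drought-risen set was lower in osbzip23 (adjusted p = 7.73e-18, and 0.0026 with an estimated correlation), and so was the drought-fallen set (adjusted p = 1.41e-06, and 0.0139 with an estimated correlation). Both sets were lower in all 10 of the shuffled fits as well, with adjusted p from 1.71e-17 to 1.05e-16 for the risen and 1.71e-06 to 1.22e-05 for the fallen set at the preset correlation, so that both observed values were smaller than those of every shuffled fit. With an estimated correlation the shuffled fits gave 0.00171 to 0.00338 for the risen and 0.00582 to 0.0176 for the fallen set, ranges that hold the observed values. Rows with counts in osbzip23 and none in wild type are higher in osbzip23 and cannot belong to either set. The lower position of both sets was therefore fixed in part by the rows tested. The comparison with independent lists carries the same limit, and no genotype effect is read from these values.

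Values that do not depend on which row a count stands on were compared without a test. At a common depth of 14653876 counts, 19742 ± 219 rows reached 10 counts in osbzip23 and 18828 ± 34.6 in wild type drought (SD, n = 2 each). The most abundant row took 1.22% ± 0.328 of counts in osbzip23 and 3.13% ± 0.0965 in wild type drought, and the 10 most abundant rows took 6.73% ± 1.19 and 8.61% ± 0.19. With 2 libraries against 2, the smallest two-sided p that an exact permutation test allows for such single values is 0.333, so none was run.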

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

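The fit of the 6 wild type samples and the shuffled osbzip23 rows were chosen after seeing the data, and all other alternatives were planned. Among recomputed counts of genes, 104 stayed within 1.5 times the value in the report and 40 did not. This tally includes the genotype comparison, also with its rows shuffled, where all counts but one with the fold minimum stayed. That stability says nothing of the wild type counts, which taken alone stayed less often than the tally shows. All 284 recomputed fold changes of named rows kept their sign and their call. These rows were chosen from the same data for the largest called folds, so this was nearly fixed by the choice. The tally includes the named rows of the genotype comparison, which are not read as effects. With a minimum absolute log2 fold change of 1, which by construction calls fewer genes, there were 9042 genes for drought against normal, 1105 for recovery against normal, 7870 drought-changed genes called back, 350 on the drought side after rewatering, 425 beyond normal, and 4249 called opposite to drought in osbzip23. Library size scaling put 1370 genes on the drought side. The following settings gave the number of genes for recovery against normal, on the drought side and beyond normal, in that order. DESeq2 gave 6954, 2098 and 3753, the 4 samples compared gave 8910, 2707 and 4690, and the 6 wild type samples gave 7968, 2455 and 4357. Apart from the fold minimum, the cause was not tested, but the common dispersion was 0.0214 with the osbzip23 libraries and 0.0056 without them.

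Leaving out each library in turn, where the lone sample left in a group is assumed to vary like the other groups, gave ranges of 10551 to 15971 genes for drought against normal, 11773 to 16708 for recovery against drought, 604 to 6517 for recovery against normal, and 29445 to 30743 for the genotype. The ranges were 9744 to 14222 genes called back, 193 to 1940 on the drought side, 314 to 3585 beyond normal, and 5266 to 8176 opposite to drought in osbzip23. Same-numbered samples of the wild type groups did not deviate together, with correlations of -0.027 to 0.004. Pairs with osbzip23 gave -0.005 to 0.008, which do not bear on this if their rows do not correspond. With the replicate block the counts were 13012, 13985, 2302 and 30377 genes for the 4 comparisons in the same order, and no count moved by over 1.5 times. The tests of gene lists and description families, with a preset or estimated correlation, and the bZIP23 level were not run under any setting because no ID was matched to a name. Depth limits the osbzip23 libraries most, where 3 counts correspond to 0.205 and 0.176 CPM, against 0.0699 to 0.0802 CPM in wild type.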

Other observations

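All tests of explanations below were chosen after the result was seen, except the test of rows shifted by up to 300. Beyond the comparisons above, a small set of wild type genes behaved as switches. Taking rows with at most 3 counts in each normal library and at least 10 CPM in each drought library, 42 genes were on in drought, with 0.636% ± 0.0274 of the drought counts (SD, n = 2). After rewatering, 30 of them had at most 3 counts in both libraries again and 0 stayed at 10 CPM or more in both. In the other direction, 30 genes with at least 10 CPM in each normal library had at most 3 counts in each drought library. Of these, 25 were back at 10 CPM or more in recovery, and the 30 together took 0.150% ± 0.000388 of the recovery counts against 0.0962% ± 0.00385 of the normal counts. Between normal and recovery the same criteria found 1 gene in each direction.

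In recovery, the upper 50% of counts came from fewer genes than in the other groups. The most abundant 905.5 ± 12.0 genes made up 50% of counts in recovery, against 1227.5 ± 9.19 in normal, 1169.5 ± 21.9 in drought and 1060.5 ± 125 in osbzip23 drought libraries (SD, n = 2 each). The difference was not tested. The 10 most abundant genes took 6.28% ± 0.0129 of counts in recovery, 4.58% ± 0.0327 in normal and 8.61% ± 0.19 in wild type drought libraries. The number of genes detected was not lowest in recovery. At an equal total, 19372 ± 49.5 genes reached 10 counts in recovery and 18828 ± 34.6 in wild type drought.

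The osbzip23 libraries had a low correlation with every wild type library, at most r = 0.116 over all rows. Loss of OsbZIP23 function as the whole cause is argued against by the wild type libraries themselves, in which at most 0.0278% of the counts in any group fell on chromosome 12 IDs. Shifts of up to 300 rows, for which a chromosome median r above 0.6 was required, gave at most 0.286 (0.255 with shuffled rows), and shifts of up to 6000 rows at most 0.364 (0.301), with a median over blocks of 0.343 (0.273) and a highest single block of 0.455 (0.339), so that a shift in these ranges is argued against as the whole cause although each of these 4 values exceeded its shuffled one, and longer shifts were not tested. What stays open, as a hypothesis, is that the osbzip23 and wild type columns list the genes in different row orders, with the IDs following the first osbzip23 library, since r over the shared rows was -0.011, inside the range of shuffled rows, and the IDs restart just after that library's last count. Exchanged labels also stay open, because r across rows does not show which sample a column holds where row orders differ, and so does an effect of the genotype besides.

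After rewatering, more drought-changed genes lay beyond normal than on the drought side, 657 against 481 among the risen and 1114 against 428 among the fallen genes, ratios of 1.37 and 2.60. Simulated unchanged groups put 0 genes on opposite sides, but they called at most 12 genes between recovery and normal, so they do not decide whether chance values of the normal libraries shared by both comparisons took part. An effect of one scaling factor between recovery and normal libraries remains a candidate explanation for the ratio in either set. Library size scaling gave 3.99 and 0.79, and median-of-ratios scaling gave 1.35 and 2.76. Median-of-ratios is hardly a separate check, since it raised recovery over normal values by 0.19 on the log2 scale, against 0.18 with TMM. Such a factor moves the 2 ratios in opposite directions. Over both sets, 1771 genes lay beyond normal against 909 on the drought side with TMM. The counts were 1841 against 938 with median-of-ratios and 2149 against 1370 with library size scaling. The excess over both sets thus stayed at the factors tried. Other factors were not tried, so these totals do not decide whether one factor could be its whole cause. Apart from scaling, a minimum absolute log2 fold change of 1 gave 0.33 and 2.31, and the lowest ratio over scalings and left-out libraries was 0.50, among risen genes without recovery replicate 1, and without normal replicate 1 or 2, recovery replicate 2 or wild type drought replicate 1 or 2 the risen ratio was 0.60, 0.58, 0.56, 0.96 and 1, while the fallen ratio stayed at 2.01 or more when any library was left out. Overshoot after rewatering and the later harvest of the recovery plants both stay open and were not tested.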
